A study of Homo sapiens with 83 samples.

How the data were processed

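Total RNA of 83 human melanoma samples was measured on Affymetrix oligonucleotide arrays, 1 array per sample. Per the labels, 31 samples were primary melanomas and 52 were melanoma metastases, all described as clinical tumour tissue. The labels give neither the patient nor the body site of a metastasis, so p-values measure the spread between these samples, and 2 samples of 1 person could not be recognised. The deposited values are linear probe set intensities for 22283 probe sets. RMA is named per the submitters' processing notes, with no version. The deposited intensity values themselves shared 1 arithmetic mean per array, 165.7, while array medians ran from 32.5 to 58.9. The values were therefore on a linear scale set to a common mean, and were not quantile-normalised as deposited. Whether a further step followed RMA, or another method made these values, is not given in the sources used here. All 83 columns of the table were used. The highest correlation between 2 arrays was 0.934, so no array was treated as a repeat of another.

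Values under 1 were set to 1 and taken to log2, as the plan made before the data were examined foresaw for linear values. Probe sets were named through the platform annotation, which listed 20114 of them. A single gene symbol stood beside 19065 probe sets, several beside 1043 and none beside 2107. Symbols were updated through gene identifiers, of which 10 found no match in the RefSeq gene table of assembly GRCh38.p14. Probe sets with several symbols were not used. Each gene was read from its probe set of highest mean, which gave 11963 genes, 4310 of them with more than 1 probe set. A background level was set after the data were seen, as the 95th percentile of the log2 values of 45 bacterial and phage control probe sets, 4.86. By that level 8464 genes had a group mean above background and 3499 did not. Where the dimmer group's mean lay below it, a fold is given as "at least", computed against the mean of the higher of background and own value on each array. No fold is given where both means lay below it. For single genes with a mean below background the text gives the bound and not the fitted difference, except where an alternative changed its sign. The number of arrays limits the precision of every mean.

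Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, metastases minus primary tumours, all samples), with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated data with 11963 genes and the same group sizes, 50 genes were changed at each size. This comparison recovered 40% of genes changed by 0.5 (log2), 94% of those changed by 1 and 100% of those changed by 2 or 4, with 5 false calls. The simulated genes varied independently, with normal noise of the same SD in both groups. Correlated genes and groups of unequal spread were therefore not covered. A set of 38 gene lists with 590 genes, 518 of them measured, was fixed before the data were examined. The lists cover keratinocytes and other skin cells, immune cells, stroma, tissues that metastases may lie in, melanocyte states and general cell processes. A sample's list score is the mean over its members of the log2 value minus the gene's mean over all samples. Scores were compared by two-sided permutation tests with 100000 resamples, adjusted over the 38 lists, and by limma's camera with preset and with estimated correlation. The spread of scores was compared by permuting absolute deviations from group medians. Within each group, list scores were set against an epidermal score, the mean of the basal keratinocyte and epidermal differentiation scores. The 3' minus 5' log2 signal of the GAPDH and ACTB control probe sets was used as a measure of RNA quality.

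Named genes followed a rule fixed before the data were examined. It took the 12 largest increases and the 12 largest decreases past the threshold, the 3 members of each list with the largest differences, and MITF, SOX10, MLANA, SPP1, CDH1, CDH2, KRT14 and MKI67. XIST and Y-linked genes were left out. Genes of families whose probe sets can cross-hybridise (immunoglobulin, HLA, cancer-testis and haemoglobin genes) are uncertain. Of 93 other probe sets of the 134 named genes, 14 differed in sign from the one used, 4 of these above background.

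Each sample title holds a number before a slash, which was treated as a possible batch. There were 29 such numbers, and 4 of them held both groups, with 9 primary tumours and 7 metastases. Alternatives planned before the data were examined were quantile normalization of the deposited values, median centring and other ways to choose probe sets. Also planned were a filter and a higher floor for dim values, array weights, rank tests and the title number as a block. Covariates for RNA quality and epidermal score, and median scores, were planned as well. Alternatives chosen after seeing the data were the background filter, an 18S ribosomal RNA covariate, both covariates together and leaving out 8 arrays of largest 3' minus 5' signal. Their permutation tests used 10000 resamples. Scores and tests were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.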

Results

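Gene expression was measured in 31 primary melanomas and 52 melanoma metastases taken from patients, with 1 array for each sample. The series title sets the work in the search for a gene signature of aggressive melanoma metastasis, and the labels divide the samples into primary tumours and metastases. Array medians averaged 44.2 ± 5.00 intensity units (SD, n = 31) in primary tumours and 45.97 ± 5.11 (SD, n = 52) in metastases.

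Genes of the epidermis were far lower in metastases than in primary tumours, markers of other skin cells were lower, and genes of cell division and protein folding were moderately higher. Camera with an estimated correlation kept the keratinocyte, junction, mast cell, skin gland, DNA repair and unfolded protein response lists. It did not keep the mitosis, DNA replication, Langerhans and dendritic cell, smooth muscle or fibroblast lists. Among genes above background in both groups, the keratin gene KRT5 had the largest decrease, a log2 difference of -6.66 ± 0.54 (SE, 101-fold). S100A7 (psoriasin), a keratinocyte protein below background on average in metastases, fell at least 64.9-fold. Among genes above background in both groups that rose, SPP1, the secreted phosphoprotein osteopontin, had the largest difference, 2.77 ± 0.42 (SE, 6.81-fold, adjusted p = 1.73e-07). With the 3' minus 5' signal and the epidermal score together as covariates SPP1 differed by -0.26 (adjusted p = 0.909). The adaptor SKAP2 rose by 1.64 ± 0.24 (3.12-fold). Of genes below background on average in primary tumours, the metalloproteinase ADAM12 rose at least 2.48-fold, the RNA-binding protein IGF2BP3 at least 2.40-fold and the transcriptional co-regulator CITED1 at least 1.77-fold. The exocyst subunit EXOC5 and the MYB-related factor MYBL1 rose at least 1.36-fold and 1.12-fold. Another ADAM12 probe set, above background in both groups, gave a log2 difference of -0.08, and with both covariates CITED1 differed by -0.30 (adjusted p = 0.896). The glycodelin gene PAEP and the ceramide galactosyltransferase UGT8 also passed the test (adjusted p = 0.00607 and 5.83e-06), with both group means below background. By limma, 3968 of 11963 genes passed the threshold, 33.2%, of which 2745 were higher in metastases and 1223 lower. At a fitted difference of at least 2-fold there were 635 genes, 227 higher and 408 lower. With genes below background taken at their bound, a count made after seeing the data, there were 347, 108 higher and 239 lower. The median difference of all genes was 0.12, and quantile normalization of the deposited values moved the split to 1998 higher and 1724 lower. With the title number as a fixed block, where only 9 primary tumours and 7 metastases share a number, 336 genes passed. With the 3' minus 5' signal as a covariate 1644 passed, with the epidermal score 623 (579 higher and 44 lower), and with both covariates 15 (13 higher and 2 lower).

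Genes of the epidermis fell together. In the basal keratinocyte list 9 of 10 measured members fell and 0 rose, and KRT5 and KRT14, the paired keratins of the basal layer, fell 101-fold and at least 92.9-fold. KRT15 fell at least 6.96-fold. All 25 measured members of the epidermal differentiation list fell, among them KRT1 (59.9-fold), the cornified envelope protein LORICRIN (at least 25.3-fold) and filaggrin, FLG (at least 12.8-fold). Activated keratinocyte genes fell in 9 of 9 cases, including KRT16 (at least 27.5-fold) and S100A8 (38.3-fold), which myeloid cells also express. Epithelial junction genes fell in 15 of 17 cases, including the desmosome genes DSP (16.4-fold), JUP (13.8-fold) and DSC2 (at least 4.55-fold), though 5 of the 17 lay below background in both groups. The epithelial cadherin CDH1 fell by 2.50 ± 0.63 on average (adjusted p = 0.00117), while CDH2 did not pass (adjusted p = 0.488). The fall of CDH1 was not uniform, with an SD of 3.54 in metastases and 0.77 in primary tumours. It lay above the median of primary tumours in 16 of 52 metastases, against 1 for DSP and 0 for JUP. Adjusted over the list alone, the counts that fell were 9, 25, 9 and 15, with 1 junction gene higher. The scores of the 4 lists differed by -3.83 ± 0.29, -3.95 ± 0.32, -4.66 ± 0.36 and -2.11 ± 0.20 (SE), each at a permutation p of 1e-05, the smallest that 100000 resamples can give, and an adjusted p of 3.45e-05. With an estimated correlation the camera calls of all 4 held (adjusted p = 0.000438 for the 3 keratinocyte lists and 0.000945 for junctions). With the epidermal score as a covariate the activated keratinocyte and junction scores differed by -0.14 and 0.26 and did not pass, and DSP differed by 0.30. With both covariates S100A8 and JUP differed by 0.0053 and 0.025. Within the 4 title numbers that held both groups, the epidermal differentiation score differed by -4.46, -2.66, -4.14 and -4.41, and the basal keratinocyte score by -4.57, -2.12, -2.70 and -3.43. KRT14 was above background in 31 of 31 primary tumours and in 13 of 52 metastases, and KRT5 in 31 and 21.

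**Figure D1:**
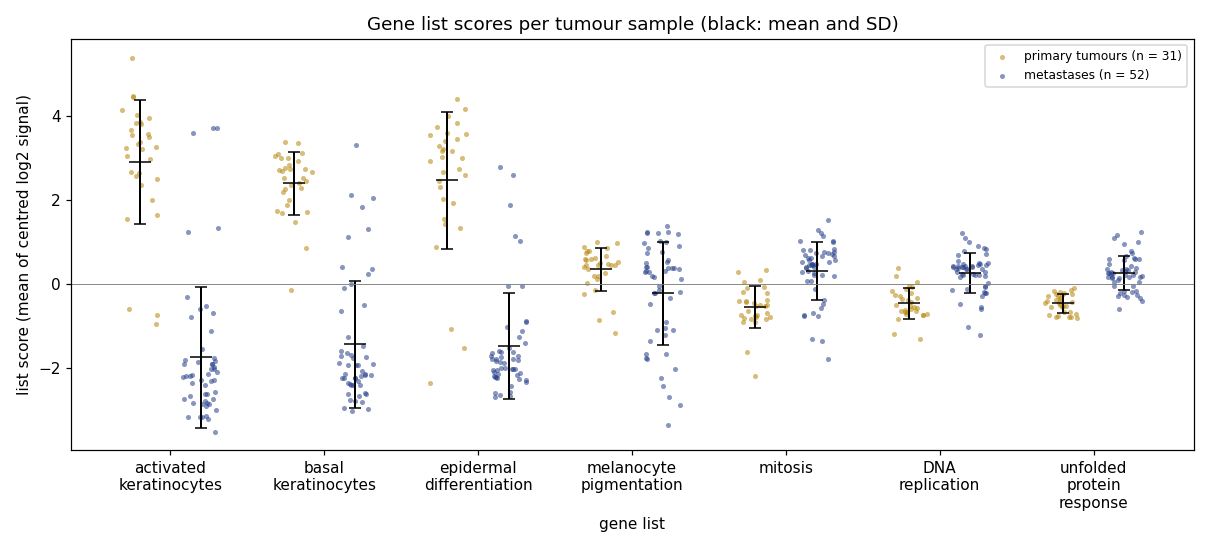
List scores of 7 gene lists in each sample, with the score (mean of centred log2 signal) on the vertical axis, points for samples, and black bars for the mean and SD of 31 primary tumours and 52 metastases. The keratinocyte lists were lower in most metastases, with a few at the level of primary tumours, and the division and protein folding lists were higher.

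Markers of other skin cells fell as well. Langerhans and dendritic cell genes fell in 6 of 8 cases, CD1C at least 1.80-fold, the IgE receptor chain FCER1A at least 2.21-fold and langerin, CD207, by 1.40 ± 0.26 on the log2 scale. Mast cell genes fell in 4 of 7 cases, including the tryptase TPSB2 (log2 difference -2.43) and cathepsin G, CTSG (at least 2.14-fold). Skin gland genes fell in 7 of 9 cases, AZGP1 at least 3.21-fold, though 7 of the 9, KRT7 and SCGB2A2 among them, lay below background in both groups. Smooth muscle genes fell in 5 of 8 cases, including MYH11, at least 2.02-fold, and CNN1, for which the background level allows no fold. Fibroblast and matrix genes fell in 12 of 22 cases, with 1 higher, and MFAP4 fell at least 2.01-fold, CFD by 2.05 and DPT by 1.39 on the log2 scale. Adjusted over the list alone, 6, 5, 8, 5 and 12 members fell. The scores differed by -1.23 ± 0.21, -1.20 ± 0.18, -1.30 ± 0.23, -0.77 ± 0.23 and -0.55 ± 0.18 (SE), with adjusted permutation p of 3.45e-05 for the first 3, 0.00261 for smooth muscle and 0.00749 for fibroblasts. With an estimated correlation, camera kept mast cells (adjusted p = 0.0367) and skin glands (adjusted p = 0.0466), and lost Langerhans and dendritic cells (adjusted p = 0.0593), smooth muscle (adjusted p = 0.302) and fibroblasts (adjusted p = 0.329). With the title number as a fixed block, smooth muscle (-0.93 ± 0.46, adjusted p = 0.271) and fibroblasts (-0.47 ± 0.36, adjusted p = 0.424) did not pass, with wider errors. Nor did smooth muscle pass with the 3' minus 5' covariate (-0.57 ± 0.30, adjusted p = 0.125). With the epidermal score as a covariate none of these 5 lists passed, and their differences ran from -0.078 for Langerhans and dendritic cells to 0.41 for skin glands. Of the genes named, SCGB2A2 (0.68), CD207 (0.47), CFD (0.64), MYH11 (0.20) and CNN1 (0.44) changed sign there and did not pass.

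Genes of cell division rose in metastases. All 24 measured mitosis genes rose, with the checkpoint kinase BUB1 at least 2.15-fold higher and the mitotic kinase CDK1 at 1.52 ± 0.24 (2.87-fold). Of 25 DNA replication genes 23 rose and 0 fell, including ribonucleotide reductase RRM2 (1.39 ± 0.20), thymidylate synthase TYMS (1.15 ± 0.21) and the sliding clamp PCNA (1.07 ± 0.15). Outside the lists, the checkpoint gene MAD2L1 (at least 2.32-fold) and the replication factor MCM10 (at least 1.19-fold), named for being among the 12 largest fitted increases, rose from means below background in primary tumours. Of 12 DNA repair genes 10 rose, FANCI by 0.94 and BRCA1 at least 1.24-fold. The proliferation marker MKI67 rose by 0.48 ± 0.10 (1.40-fold, adjusted p = 5.32e-05). Adjusted over the list alone, 24, 24 and 10 members rose. Scores differed by 0.87 ± 0.14 for mitosis, 0.72 ± 0.10 for DNA replication and 0.65 ± 0.09 for DNA repair (SE, adjusted permutation p = 3.45e-05 each). With an estimated correlation, camera kept DNA repair (adjusted p = 0.0466) but not mitosis (adjusted p = 0.148) or DNA replication (adjusted p = 0.0718). The mitosis score lay above the median of primary tumours in 44 of 52 metastases. Within the 4 title numbers with both groups, the mitosis score differed by 0.74, 1.18, 1.09 and 0.66, and the DNA replication score by 0.70, 0.88, 0.85 and 0.75. With the epidermal score as a covariate the mitosis difference was 0.73 ± 0.26 (adjusted p = 0.0603) and that of DNA repair 0.38 ± 0.15 (adjusted p = 0.081). The 3' minus 5' signal, a sign of RNA degradation, was also lower in metastases, by a log2 difference of -0.65. With it as a covariate mitosis differed by 0.75 ± 0.19 and DNA replication by 0.62 ± 0.13, and with both covariates by 0.59 ± 0.29 (adjusted p = 0.196) and 0.54 ± 0.20 (adjusted p = 0.136), and DNA repair by 0.32 (adjusted p = 0.224).

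Genes of the unfolded protein response, which raise the folding capacity of the endoplasmic reticulum, rose in 12 of 14 cases, the same count adjusted over the list alone. The chaperone HSP90B1 rose by 1.42 ± 0.18 (2.68-fold), and by 0.76 in its other probe set. The disulphide isomerase PDIA6 rose by 1.12 ± 0.14 (2.17-fold) and asparagine synthetase, ASNS, by 0.99 ± 0.29. The score differed by 0.72 ± 0.08 (SE, adjusted permutation p = 3.45e-05), and camera with an estimated correlation kept the call (adjusted p = 0.0367). It lay above the median of primary tumours in 51 of 52 metastases, and within the 4 shared title numbers it differed by 0.94, 0.44, 0.90 and 0.54. With the 3' minus 5' signal and the epidermal score together as covariates the difference was 0.55 ± 0.16 (adjusted p = 0.0252). Oxidative phosphorylation genes rose in 11 of 24 cases, 12 adjusted over the list alone, with the complex I subunits NDUFB5 (1.02 ± 0.12) and NDUFB3 (0.61 ± 0.10) and the oxidase subunit COX7B (0.53 ± 0.19). Their score differed by 0.27 ± 0.06 (adjusted permutation p = 6.33e-05; adjusted p = 0.416 with an estimated correlation in camera), and with both covariates it was 0.25 (adjusted p = 0.194). Cancer-testis antigens, germline genes that tumours can express, rose in 3 of 12 cases, MAGEA6 by 1.89, MAGEA12 by 1.49 and MAGEB2 at least 1.31-fold, and the score differed by 0.53 ± 0.19 (adjusted p = 0.0135). For this list camera gave an adjusted p of 0.378 with a preset correlation and an adjusted p of 0.717 with an estimated correlation. The score difference was 0.30 (adjusted p = 0.071) without x_at or s_at probe sets, from which MAGEA6 and MAGEA12 were read, and 0.39 (adjusted p = 0.0513) with median scores. It was 0.33 (adjusted p = 0.28) with the 3' minus 5' covariate, 0.34 (adjusted p = 0.592) with the epidermal covariate, 0.11 (adjusted p = 0.956) with both, 0.19 (adjusted p = 0.854) with the fixed block and 0.49 (adjusted p = 0.0508) without the 8 arrays of largest 3' minus 5' signal.

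**Figure D2:**
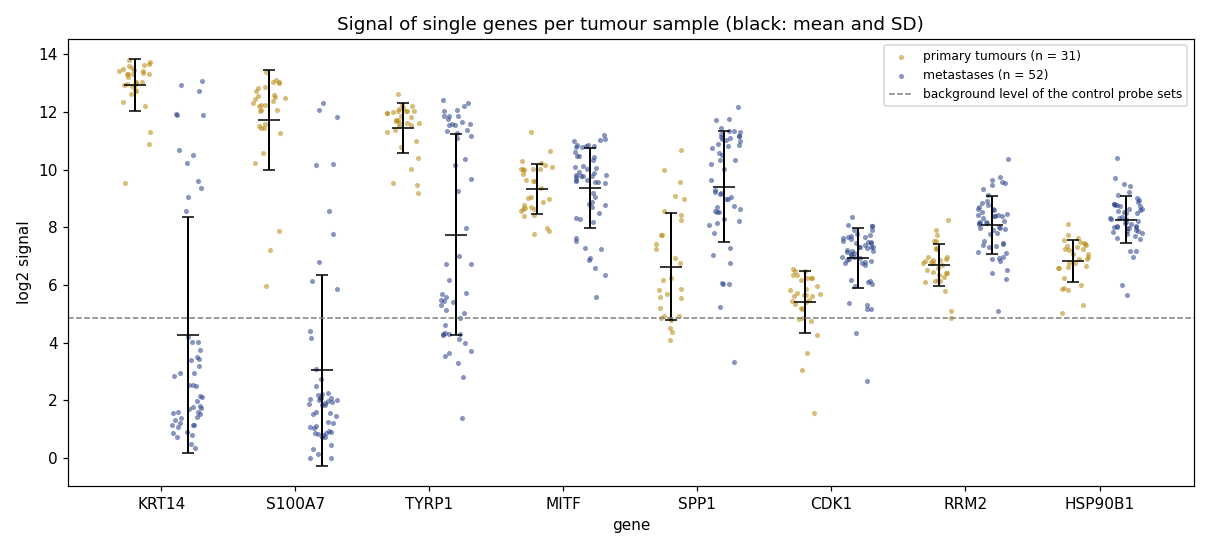
Log2 signal of 8 genes in each sample, with points for samples, black bars for the mean and SD of 31 primary tumours and 52 metastases, and a dashed line at the background level of 4.86. TYRP1 ranged widely among metastases (SD 3.47 against 0.87 in primary tumours), and CDK1, RRM2 and HSP90B1 were shifted upward.

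Of the melanocyte genes, a minority changed. The melanin enzyme TYRP1 fell by 3.71 ± 0.62 (13.1-fold), the melanosome protein PMEL by 1.47 ± 0.49 and the transporter OCA2 by 1.28 ± 0.39. PMEL differed by 0.60 with the title number as a fixed block (adjusted p = 0.853), and OCA2 by 0.86 with the epidermal score as a covariate (adjusted p = 0.439). The lineage factors MITF (0.03 ± 0.27, adjusted p = 0.946) and SOX10 (0.19 ± 0.28, adjusted p = 0.64) did not pass the test, nor did MLANA (-0.90 ± 0.44, adjusted p = 0.108). Of 21 measured pigmentation genes 5 fell and 1 rose, also adjusted over the list alone, and the score differed by -0.57 ± 0.23 (adjusted p = 0.0277; adjusted p = 0.486 with an estimated correlation in camera). Within the 4 shared title numbers it differed by -0.39, 0.84, -0.17 and -1.04, and by -0.04 with the number as a fixed block. The pigmentation call was also lost by the rank test (adjusted p = 0.0857) and with median scores (-0.27, adjusted p = 0.285). Among 14 genes of dedifferentiated melanoma 4 fell, among them EGFR (-2.86), SOX9 (-1.56) and WNT5A (-1.07), which skin cells also express. That score differed by -0.51 ± 0.14 (adjusted p = 0.00139; adjusted p = 0.283 with an estimated correlation in camera). It was -0.31 without x_at or s_at probe sets (adjusted p = 0.0608), and with the epidermal covariate the pigmentation and dedifferentiated scores differed by -0.18 and -0.011 and did not pass. EGFR and WNT5A then differed by 0.059 and 0.12. Without covariates, other EGFR probe sets with a group mean above background differed by -0.87 and -0.055.

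Of the remaining immune lists, only MHC class II presentation passed the permutation test. Macrophage genes rose in 3 of 15 cases, the complement receptor VSIG4 by 1.06 and FCGR2A by 0.86, with a score difference of 0.39 ± 0.20 (adjusted p = 0.0959). T cell genes fell in 1 of 12 cases (IL7R, -0.89), and the scores of T cells (-0.40, adjusted p = 0.229), cytotoxic lymphocytes (-0.04, adjusted p = 0.889), B cells (0.44, adjusted p = 0.211) and plasma cells (0.50, adjusted p = 0.304) did not pass. The lymphoid chemokines CCL19 and CCL21 fell by 2.02 and 1.51, and their list differed by -0.69 ± 0.35 (adjusted p = 0.0855). MHC class II genes fell in 4 of 11 cases, including the invariant chain CD74 (-0.76), with a score of -0.49 ± 0.21 (adjusted p = 0.0357; adjusted p = 0.474 with an estimated correlation in camera). That call was also lost with the mean over probe sets (-0.43, adjusted p = 0.1), without x_at or s_at probe sets (-0.37, adjusted p = 0.138) and with median scores (-0.42, adjusted p = 0.0965). The same held with the fixed block (-0.54 ± 0.47, adjusted p = 0.479) and with the 3' minus 5' covariate (-0.47 ± 0.27, adjusted p = 0.151). It held too with the 18S covariate (-0.53 ± 0.25, adjusted p = 0.0582) and without the 8 arrays (-0.42, adjusted p = 0.115). Of 11 MHC class I genes 3 fell, HLA-B and HLA-E by 0.61 and HLA-C by 0.47, and the score did not pass (-0.19, adjusted p = 0.353). The interferon score also did not pass (-0.10, adjusted p = 0.706), with IFI27 lower (-1.39) and IFI35 higher (0.42). Of 15 immediate early genes 5 fell, KLF4 by 2.15 and ZFP36 by 1.27, with a score of -0.43 ± 0.11 (adjusted p = 0.000497; adjusted p = 0.174 with an estimated correlation in camera). With the epidermal score as a covariate MHC class II (-0.20, adjusted p = 0.779) and immediate early genes (-0.12, adjusted p = 0.76) did not pass, and IFI35 differed by -0.018.

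**Figure D3:**
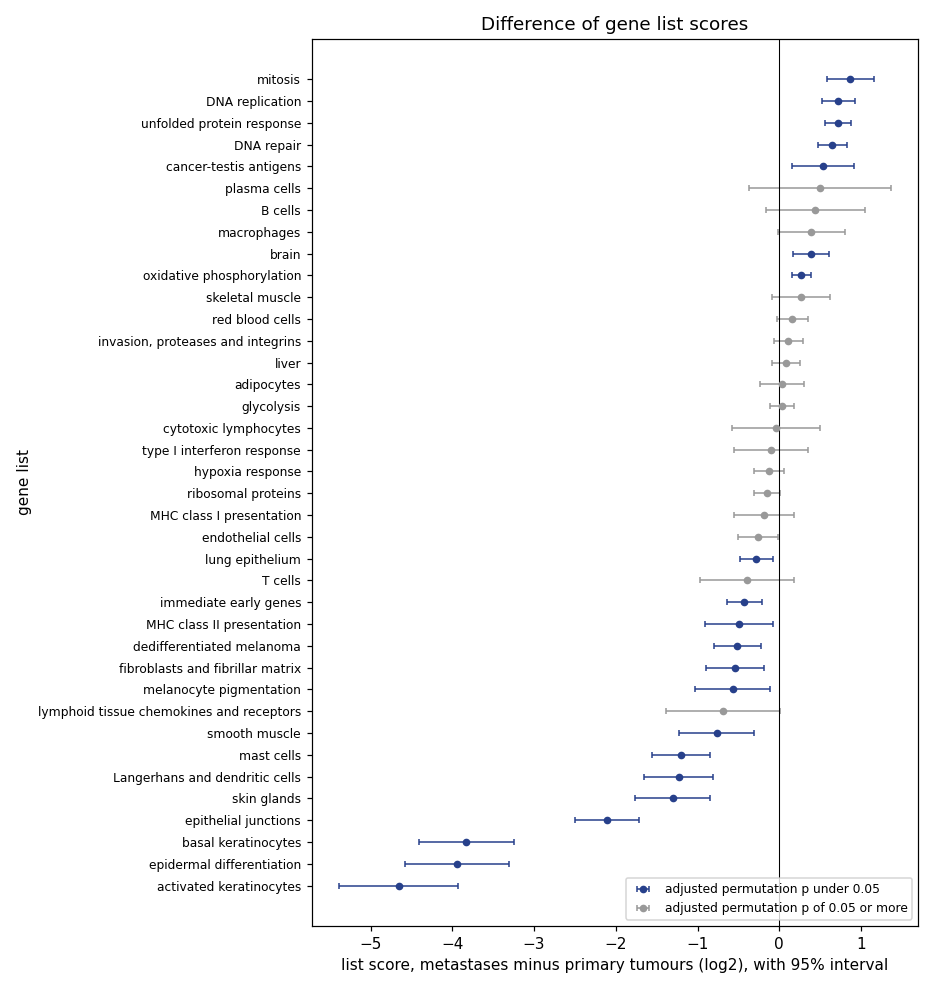
Difference of each of the 38 list scores (metastases minus primary tumours, log2) on the horizontal axis, with 95% intervals, blue where the adjusted permutation p was under 0.05. Of the 38 lists, 7 were higher and 14 lower, from -4.66 for activated keratinocytes to 0.87 for mitosis, and camera with an estimated correlation kept 8 of them, 2 higher and 6 lower.

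Markers of tissues in which metastases may lie showed small differences. The brain list was higher by 0.39 ± 0.11 (adjusted p = 0.00136; adjusted p = 0.661 with an estimated correlation in camera), with GFAP and MOG past the threshold but below background in both groups, and the fixed block gave an adjusted p of 0.732. The lung list differed by -0.28 ± 0.10 (adjusted p = 0.0134; adjusted p = 0.213 with an estimated correlation in camera), with SFTPC at -0.48 and 4 of 6 members below background in both groups, and the fixed block gave an adjusted p of 0.518. With the epidermal score as a covariate the brain and lung scores differed by 0.50 (adjusted p = 0.081) and 0.22 (adjusted p = 0.507), and with only genes above background by 0.22 (adjusted p = 0.0805) and -0.22 (adjusted p = 0.126). The brain score was 0.12 with the mean over probe sets (adjusted p = 0.222) and the lung score -0.14 with the 3' minus 5' covariate (adjusted p = 0.364). Liver (0.08, adjusted p = 0.394), skeletal muscle (0.26, adjusted p = 0.203), adipocytes (0.03, adjusted p = 0.826), red blood cells (0.16, adjusted p = 0.151) and endothelial cells (-0.26, adjusted p = 0.0721) did not pass. With a preset correlation camera called endothelial cells (adjusted p = 0.0185), T cells (adjusted p = 0.032), lymphoid chemokines (adjusted p = 0.0411) and MHC class I (adjusted p = 0.0474) lower, and with an estimated correlation none of these 4 (adjusted p from 0.416 to 0.661). In the adipocyte list FABP4 rose at least 1.29-fold and CIDEA fell at least 2.00-fold, though CIDEA differed by 0.23 with both covariates. Invasion genes went both ways, 5 higher and 3 lower of 20, with the collagenase MMP1 at least 1.04-fold lower and the gelatinase MMP2 at -1.19, and a score of 0.11 (adjusted p = 0.268) beside a member median of -0.01. Of 13 glycolysis genes 1 rose and 2 fell, and the score was 0.03 (adjusted p = 0.706), with PGK1 higher by 0.54 and SLC2A1, the glucose transporter, lower (-0.79). Of 11 hypoxia genes 1 rose and 4 fell, and the score was -0.12 (adjusted p = 0.233) while its member median was 0.17, with EGLN3 at -0.83 and ANGPTL4 at least 1.27-fold lower. SLC2A1 and EGLN3 differed by 0.20 and 0.22 with the epidermal covariate, and PGK1 and ANGPTL4 by -0.014 and 0.28 with both covariates, none past the threshold. Of 23 ribosomal protein genes 8 fell and 1 rose, RPL14 (-0.52) and RPL27 (0.55) among them. Their score was -0.15 (adjusted permutation p = 0.102), and camera called the list lower with a preset correlation (adjusted p = 0.000794) but not with an estimated correlation (adjusted p = 0.486).

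Array controls that follow RNA quality differed between the groups. The 3' minus 5' signal of GAPDH was 0.83 ± 0.43 (SD, n = 31) in primary tumours and 0.20 ± 0.28 (SD, n = 52) in metastases, and that of ACTB 1.28 ± 0.58 and 0.61 ± 0.38. Both differences had an adjusted permutation p of 0.000122, as did 18S ribosomal RNA signal, 11.1 ± 1.29 against 8.38 ± 2.53. Of 45 bacterial and phage control probe sets 1 differed. The mean 3' minus 5' signal correlated with group membership at r = -0.64 and the epidermal score at r = -0.83, across the samples of both groups.

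The spread between samples differed for 4 lists. Metastases varied more in melanocyte pigmentation (SD 1.22 against 0.51, adjusted permutation p = 0.0123; adjusted p = 0.0579 with median scores), MHC class I (0.94 against 0.51, adjusted p = 0.0151) and fibroblast genes (0.91 against 0.53, adjusted p = 0.0371). Skin gland genes varied less in metastases (0.67 against 1.42, adjusted p = 0.00608). Of the 9 measured skin gland genes 7 had means below background in both groups, so this comparison rests largely on dim signal. The SD of the B cell score was 1.64 in metastases and 0.57 in primary tumours (adjusted p = 0.0717).

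Within each group, other lists were set against the epidermal score in 72 relations. Among primary tumours (n = 31) 17 lists passed the adjusted threshold by Pearson r, and fewer passed by Spearman rho. Mast cells, for example, gave r = 0.52 but rho = 0.32 (permutation p = 0.0801), and r was 0.11 without the 2 samples farthest from the median. Epithelial junctions followed the score closely (Pearson r = 0.94, permutation p = 1e-05, adjusted p = 0.000144; Spearman rho = 0.87, permutation p = 1e-05), and r was 0.90 without the 2 samples farthest from the median. Langerhans and dendritic cells gave r = 0.67 (permutation p = 8e-05, adjusted p = 0.000823; rho = 0.53, p = 0.0026), and 0.43 without those 2. Mitosis gave r = 0.45 (permutation p = 0.0155, adjusted p = 0.0447) but rho = 0.16 (p = 0.38), and DNA replication r = 0.43 (p = 0.0162) but rho = 0.23 (p = 0.21), so neither held by rank, and r was 0.39 and 0.18 without those 2. Among metastases (n = 52) 9 lists passed by Pearson r. Skin glands gave r = 0.71 (permutation p = 1e-05, adjusted p = 0.000144; rho = 0.45, p = 0.00079) and mast cells r = 0.54 (p = 3e-05, adjusted p = 0.00036; rho = 0.52, p = 0.00012), with r of 0.60 and 0.48 without the 2 farthest samples. MHC class I gave r = -0.34 (p = 0.0126, adjusted p = 0.04; rho = -0.57, p = 5e-05) and -0.41 without them.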

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

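The background filter, the 18S ribosomal RNA covariate, the pair of covariates together and the left-out arrays were chosen after seeing the data, and the other alternatives before the data were examined. Both counts of called genes stayed within 1.5 times of 3968 and 635 under quantile normalization, median centring, array weights and the rank test. They also did so with the mean over probe sets, the random block, the background filter and without the 8 arrays of largest 3' minus 5' signal. The cause of the changes below was not tested unless a sentence gives it. Dim signal is a limit: 3499 of 11963 genes had no group mean above background.

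Without probe sets named x_at or s_at, which leaves 8369 genes, 2434 passed, 1676 higher and 758 lower. With dim genes left out, which keeps 7975, 394 genes differed at least 2-fold, 146 higher and 248 lower, and with a floor at the 20th percentile 149 were at least 2-fold higher. Fewer or compressed genes are part of these settings. With the title number as a fixed block 336 genes passed, 151 higher and 185 lower, and 271 at least 2-fold, 96 higher and 175 lower. In only the samples of shared numbers 245 passed, 106 higher and 139 lower, and 239 at least 2-fold, 101 higher and 138 lower. Only 9 primary tumours and 7 metastases bear on these fits. With the 3' minus 5' covariate 1644 passed, 951 higher and 693 lower. With the epidermal covariate 623 passed, 579 higher and 44 lower, and 231 at least 2-fold, 17 of them lower. With the 18S covariate 1782 were higher. With both covariates 15 passed, 13 higher and 2 lower, and 10 at least 2-fold, 8 higher and 2 lower. The covariates track the groups (r = -0.64 and -0.83), which tends to widen the errors, but differences shrank as well. With the epidermal covariate the SE of the mitosis difference grew from 0.14 to 0.26. The SE of the junction difference went from 0.20 to 0.16, while the difference went from -2.11 to 0.26. For activated keratinocytes the SE went from 0.36 to 0.25 and the difference from -4.66 to -0.14. The latter 2 calls were lost through the smaller difference and not through a wider error.

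Of the 38 lists, 7 were higher and 14 lower. The fixed block left 9 lower in all samples and 9 in the shared numbers, the epidermal covariate 3 higher and 0 lower, and both covariates 1 higher and 0 lower. The basal keratinocyte and epidermal differentiation lists make up that covariate and were not tested with it. All list calls held their direction and side of the threshold with the 20th percentile floor and the random block. Lists that lost the call were, by score difference, as follows. With the mean over probe sets these were MHC class II -0.43 and brain 0.12. Without x_at or s_at probe sets they were MHC class II -0.37, dedifferentiated melanoma -0.31 and cancer-testis antigens 0.30. Without dim genes it was lung epithelium -0.22, and by the rank test melanocyte pigmentation -0.57. With median scores they were MHC class II -0.42, melanocyte pigmentation -0.27 and cancer-testis antigens 0.39. With the fixed block they were MHC class II -0.54, fibroblasts -0.47, smooth muscle -0.93, lung epithelium -0.20, brain 0.18, melanocyte pigmentation -0.036 and cancer-testis antigens 0.19, with equal values in the shared numbers alone. With the 3' minus 5' covariate they were MHC class II -0.47, smooth muscle -0.57, lung epithelium -0.14 and cancer-testis antigens 0.33. With the epidermal covariate they were activated keratinocytes -0.14, Langerhans cells -0.078, MHC class II -0.20, brain 0.50, melanocyte pigmentation -0.18, dedifferentiated melanoma -0.011, mitosis 0.73, DNA repair 0.38, cancer-testis antigens 0.34 and immediate early genes -0.12. With the background filter they were lung epithelium -0.22 and brain 0.22, and with the 18S covariate MHC class II -0.53. With both covariates they were activated keratinocytes -0.080, mast cells -0.019, MHC class II -0.16, fibroblasts -0.075, brain 0.47, melanocyte pigmentation -0.40, dedifferentiated melanoma -0.098, mitosis 0.59, DNA replication 0.54, DNA repair 0.32, cancer-testis antigens 0.11, oxidative phosphorylation 0.25 and immediate early genes -0.030. Without the 8 arrays they were MHC class II -0.42, lung epithelium -0.24 and cancer-testis antigens 0.49.

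Lists that changed sign, none past the threshold, were epithelial junctions 0.26, skin glands 0.41, mast cells 0.080, fibroblasts 0.091, smooth muscle 0.31 and lung epithelium 0.22 with the epidermal covariate, and epithelial junctions 0.25, skin glands 0.73, Langerhans cells 0.21, smooth muscle 0.56 and lung epithelium 0.39 with both covariates. Lists that gained a call were endothelial cells -0.33 and hypoxia response -0.23 after quantile normalization, and endothelial cells -0.32 after centring. Without x_at or s_at probe sets B cells 0.53 and macrophages 0.46 gained a call. Without dim genes lymphoid chemokines -0.95, endothelial cells -0.31, red blood cells 0.30 and invasion genes 0.25 did. Array weights added endothelial cells -0.29, the rank test lymphoid chemokines -0.69 and endothelial cells -0.26, the background filter endothelial cells -0.31 and median scores lymphoid chemokines -0.84.

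Of the 110 named genes called, 105 stayed called after quantile normalization, 107 after centring, 76 with the 3' minus 5' covariate and 32 with the fixed block. Of the 101 outside the lists that make up the epidermal score, 14 stayed called by limma with the epidermal covariate and 0 with both covariates, where 26 had an unadjusted p under 0.05. Genes that changed sign were HLA-DQB1 (0.078) without x_at or s_at probe sets, and PMEL (0.60) with the fixed block and in the shared numbers alone. With the epidermal covariate they were LY6D 0.19, DSP 0.30, SCGB2A2 0.68, CD207 0.47, IFI35 -0.018, CFD 0.64, MYH11 0.20, LMOD1 0.018, CNN1 0.44, OCA2 0.86, EGFR 0.059, WNT5A 0.12, RAD51AP1 -0.079, SLC2A1 0.20 and EGLN3 0.22. With both covariates they were SPP1 -0.26, CITED1 -0.30, LY6D 0.32, S100A8 0.0053, DSP 0.46, JUP 0.025, SCGB2A2 1.02, CD207 0.91, IFI35 -0.18, CLDN5 0.042, CFD 1.04, CIDEA 0.23, MYH11 1.10, LMOD1 0.32, CNN1 0.79, SFTPD 0.28, OCA2 1.00, EGFR 0.29, SLC2A1 0.28, PGK1 -0.014, ANGPTL4 0.28, EGLN3 0.30 and DUSP1 0.029. The wider spread of melanocyte pigmentation (SD difference 0.71) was 0.57 with median scores (adjusted p = 0.0579). After centring, 2 control probe sets passed instead of 1.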

Other observations

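The tests of dilution for the unfolded protein response list, and those of both measures together, were chosen after the results they build on had been seen. The other tests were set out before.

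For genes of the keratinocyte lists, different numbers of metastases were above background. These numbers do not rank the genes, since different probe sets were held against 1 common background level. KRT14 was above it in 13 of 52 metastases, KRT5 in 21, S100A7 in 10 and FLG in 10, while KRT1 was in 36 and S100A8 in 35. SPRR1A (50), KRT10 (52) and SFN (52), chosen after their values were seen, were above it in most or all. Among metastases the skin gland list followed the epidermal score (r = 0.71) and so did the mast cell list (r = 0.54). The labels give no body site, so whether these samples came from skin was not tested. The complement receptor gene CR2, carried by B cells, was above background in 0 of 31 primary tumours and 12 of 52 metastases (adjusted p = 0.0546, both group means below background), and TYRP1 in 31 of 31 and 37 of 52.

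Keratinocyte genes were lower in metastases. The account that keratinocytes lay in the primary samples needs the basal and differentiation scores to move together among primary tumours. They did, as this account requires (r = 0.77, 95% interval 0.58 to 0.88, permutation p = 1e-05). By rank rho was 0.56 (permutation p = 0.00135), and r was 0.51 without the 2 farthest samples. The scores would also move together if other cells expressed both lists, so this relation does not tell such accounts apart. Lower RNA quality of the primary samples is argued against, since the epidermal differentiation difference was -3.95 ± 0.32 without and -4.07 ± 0.42 with the 3' minus 5' covariate (95% interval -4.90 to -3.24). Batch as given by the title number is argued against in the same way, at -3.81 ± 0.75 with the fixed block (95% interval -5.31 to -2.31). A difference of the tumour cells themselves stays open, since a tissue sample does not say which cells held the RNA.

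Mitosis and DNA replication genes were higher in metastases, by 0.80 ± 0.12 for the mean of both scores, though camera with an estimated correlation called neither list (adjusted p = 0.148 and 0.0718). Dilution of tumour RNA by epidermis, read from the slope on the epidermal score within groups, predicts 0.11 (95% interval -0.25 to 0.46), and RNA quality predicts 0.11 (-0.09 to 0.31), both short of the difference. Both together predict 0.23 (-0.19 to 0.65), and 0.57 ± 0.24 remains, but the mitosis and DNA replication calls were lost there because the error grew and the difference shrank. With the title number as a fixed block the difference was 0.86 ± 0.27. The dilution predictions used 1 epidermal slope for both groups. Yet mitosis followed the epidermal score at Pearson r = 0.45 in primary tumours and r = -0.26 in metastases, and DNA replication at r = 0.43 and r = -0.23. These predictions therefore do not decide for or against dilution. The epidermal score and the 3' minus 5' signal are noisy stand-ins for what they track, which pulls such predictions toward 0. Among primary tumours dividing epidermal cells may also add to both scores. A part played by dilution or RNA quality therefore stays open beside a difference between tumour stages.

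Unfolded protein response genes were higher by 0.72 ± 0.08. Dilution predicts 0.083 (95% interval -0.16 to 0.32), RNA quality 0.073 (-0.06 to 0.21) and both together 0.17 (-0.12 to 0.45), each short of the difference, and the fixed block gave 0.72 ± 0.21. The block value argues against batch as the whole cause. Dilution and RNA quality were read from noisy stand-ins, which pulls predictions toward 0, and from 1 slope for both groups. Yet the score followed the epidermal score at r = 0.33 (adjusted permutation p = 0.136) in primary tumours and r = -0.19 (adjusted permutation p = 0.26) in metastases. The predictions therefore do not decide for or against dilution or RNA quality. The plasma cell score differed by 0.50 ± 0.44 (adjusted p = 0.304), 1 of 9 members rose, and it lay above the median of primary tumours in 29 of 52 metastases, against 51 of 52 for the unfolded protein response, while IGKC and IGLC1 differed by 0.10 ± 0.57 and 0.04 ± 0.66. The errors are too wide to exclude a part played by such cells, so a change in tumour cells is a hypothesis beside it.

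Chance can be excluded for the counts of called genes: of 100 splits of the samples into groups of the same sizes, the real one included, 1 gave as many genes as the real 3968, and 1 gave as many as the real 635 at 2-fold. The highest count of any other split was 1 in each case.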
